A study of Mus musculus with 12 samples.

How the data were processed

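RNA was sequenced from left ventricles of male mice in 4 groups of 3 libraries, with groups and replicate numbers taken from the sample titles and genotype and treatment labels. Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with a TruSeq stranded mRNA kit, which selects polyadenylated RNA. Per the submitters' processing notes, the tools named are HISAT2, an aligner, and DESeq, with the genome build GRCm38. Their versions, the gene annotation, the counting tool and whether counting used the strand are not given in the sources used here. The authors deposited raw gene counts as whole numbers, 1 table for mCKO with CTR1 (17260 genes) and another for iCKO with CTR2 (17325 genes), of which 16673 genes were in both. Every gene had at least 1 count in its table, and of the 17167 genes of the mCKO table found in RefSeq 99.1% were protein coding. Gene symbols and Gene Ontology terms were those of the deposited tables, and coordinates came from the RefSeq annotation of GRCm38. Library totals lay between 19682268 and 25871882 counts. A count of 0 in a library allows up to 3 counts, between 0.106 and 0.157 TMM-scaled CPM, a limit that covers counting error only. No pair of libraries within a group agreed within sampling noise, the closest being CTR1 replicates 1 and 2 with a chi-square of 6.49 per degree of freedom.

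CPM and log2 values were computed here from those deposited counts, with TMM-scaled library sizes for CPM and a prior count of 2 for log2 CPM. Genes were kept by filterByExpr (minimum count 10, minimum total 15), and tested by edgeR 4.0.16 quasi-likelihood fits with robust dispersions in R 4.3.3. All adjusted p-values are two-sided Benjamini-Hochberg values, called at 0.05, and every log2 fold change is given with its standard error after ± unless SD is named. Designs, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The mCKO and iCKO experiments were fitted separately without covariates. The difference between models was the contrast of mCKO against CTR1 minus iCKO against CTR2 in 1 fit of all 12 libraries over the 16673 genes in both tables. The replicate number as a block was an alternative. Same-numbered libraries of mCKO and CTR1 deviated together across genes from their group means (r = 0.464, 0.532 and 0.823 for numbers 1, 2 and 3), each over the limit of 0.1 set for pairing, so block results stand beside the others in that experiment. Libraries 1 and 2 correlated across numbers as well (0.529 and 0.553), and either with number 3 at -0.623 to -0.680, so the pairing shown by the data is of replicate 3. The labels do not say what a number marks.

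Of 34 gene lists for cardiac function, metabolism, stress, matrix and other cell types, 33 were tested with camera in limma 3.58.1 (preset correlation 0.01, adjusted over the lists of a comparison), again with an estimated correlation, and with fry. The 13 mitochondrially encoded mRNAs were not analysed here. No list was called in mCKO or iCKO with an estimated correlation, and 5 were in the difference between models, namely fatty acid oxidation, ketone and branched-chain amino acid catabolism, stress and fetal-programme, cytosolic heat shock and skeletal muscle genes. With the replicate block none of these 5 was called at an estimated correlation (lowest adjusted p = 0.12). A few genes sit in more than 1 list, and the ventricle itself expresses some markers assigned to other cell types. Genes named followed a fixed rule. It took Ddx5, Ddx17 and Camk2d, and the 10 genes with the highest and the 10 with the lowest log2 fold change per comparison among called genes with average log2 CPM of at least 1, no overlap of groups and a non-clone symbol. It added up to 4 called members with the smallest adjusted p per list (or the 2 most abundant where fewer than 2 were called), the 10 genes called in 1 direction in both models whose smaller absolute log2 fold change was largest, the 5 called in opposite directions with the largest difference, and the 5 with the smallest adjusted p in each direction of the difference. The rule gave 235 genes, and the 78 named here were chosen among them after their values and exon overlaps were seen, to keep the text short and to avoid some overlapping genes. Some genes given by the rule are not reported here. For mCKO the rule was applied to calls of the block, because none was made without it.

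Exon overlaps, gene lengths and GC content came from GENCODE M21 on GRCm38. The fits were tested on counts simulated from the real means and library sizes with 200 changed genes, 50 per fold. Changed genes had average log2 CPM of at least 1, so lower genes were not covered. Genes were drawn independently, and without the block the simulated means held no shared shift of replicate 3. Recovery without the block therefore does not describe the real mCKO fit, which called 0 genes. Changes of 1.5, 2, 4 and 8-fold were recovered at 2, 62, 96 and 96% for mCKO without the block, and at 74, 96, 100 and 98% with it. For iCKO recovery was 4, 48, 100 and 100%, and for the difference between models 2, 16, 82 and 98%. The real fits called 6068 genes in iCKO, 2892 for the difference and 1839 in mCKO with the block, against 200 changed here. Benjamini-Hochberg adjustment is less strict when more genes change, so these recovery shares do not describe those real fits. False calls numbered 7 of 135 for mCKO without the block, 16 of 200 with it, 13 of 139 for iCKO and 6 of 105 for the difference. Each share lay above the 0.05 aimed at, but each fit was simulated in a single draw, so the spread of these shares is not known. Alternatives were DESeq2 1.42.0, limma-voom, RLE factors, library sizes only, no low-count filter, CPM of at least 1 in 3 libraries, counts thinned to the smallest library, a fold threshold, 1 fit of all 12 libraries, the block, and leaving out each library. Added after seeing the data were replicate 3 as a batch term, leaving out both libraries of a number, the alternatives run with the block, the block in mCKO only for the overlap, a gene length correction (lowess span 0.3) and Gene Ontology terms with 15 to 500 genes. Ddx5, Ddx17 and Camk2d were also tested by two-sided exact permutation of their CPM, which gave 0.4 for Ddx17 and 0.5 for Camk2d in mCKO and 0.2 and 0.7 in iCKO. Alternative splicing, which the series design names, was not analysed here.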

Results

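Ddx5 encodes an RNA helicase of the DEAD-box family that acts in transcription and in pre-mRNA splicing. To examine its role in the heart, the study deleted floxed Ddx5 alleles with Cre recombinases driven by the cardiomyocyte promoter of Myh6, and sequenced RNA from the left ventricle of male mice. The 12 libraries fell into 4 groups of 3. The constitutive knockout (mCKO) carried Myh6-Cre and was taken at 8 weeks of age without treatment, beside age-matched floxed controls lacking Cre (CTR1). The inducible knockout (iCKO) carried Myh6-MerCreMer, a Cre fused to hormone-binding domains of the oestrogen receptor that enters the nucleus when tamoxifen is bound. These mice and their floxed controls without Cre (CTR2) received tamoxifen at 20 mg/kg/day for 5 days. The design text gives 7 days of tamoxifen before collection, and does not say from which injection the days were counted. Each library held between 19682268 and 25871882 gene counts. The labels do not say that the replicates of a group were separate animals, so that p-values measure the spread between these samples. In the mCKO experiment the leading principal component (59.8% of variance) set replicate 3 of both groups apart from replicates 1 and 2, and the next (22.1%) separated mCKO from CTR1. In the iCKO experiment the leading component (79.7%) separated iCKO from CTR2.

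The targeted gene was lower in every knockout library. Ddx5 (Entrez 13207, protein coding, chromosome 11, 106780355 to 106789185 in GRCm38) was measured in CTR1 at 636, 636 and 397 CPM (gene counts scaled to a common library size) and in mCKO at 233, 232 and 218 CPM. Mean levels were 556 ± 138 CPM in CTR1 and 228 ± 8.38 CPM in mCKO (SD, n = 3), 40.9% of control. CTR2 libraries held 566, 697 and 597 CPM and iCKO libraries 216, 219 and 192 CPM, with means of 620.0 ± 68.2 and 209 ± 14.8 CPM (SD, n = 3), 33.7% of control. All knockout libraries lay below all of their controls (two-sided exact permutation p = 0.1 in each model, the smallest that 3 against 3 allows). The log2 fold change in iCKO was -1.57 ± 0.15, adjusted p = 1.7e-04 (edgeR quasi-likelihood, Benjamini-Hochberg). In mCKO it was -1.29 ± 0.20 (adjusted p = 0.17) without a replicate block and -1.26 ± 0.12 (adjusted p = 0.0019) with it. These counts cover the whole gene in all cells of the tissue, and the labels do not name the floxed exons. Ddx17, the close paralog of Ddx5 (Entrez 67040, protein coding, chromosome 15, 79527696 to 79546764), rose in mCKO with the replicate block (0.38 ± 0.07, adjusted p = 0.0054), but was not called without it (0.36 ± 0.30, adjusted p = 0.88). Its change in iCKO did not pass the test (0.48 ± 0.20, adjusted p = 0.087). Camk2d, the calcium/calmodulin-dependent kinase gene whose splicing the series title names (Entrez 108058, protein coding, chromosome 3, 126595487 to 126846326), was not called in mCKO (-0.13 ± 0.06, adjusted p = 0.21 with the block) or in iCKO (-0.08 ± 0.21, adjusted p = 0.78). Gene counts do not separate its isoforms, and splicing was not analysed here.

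**Figure D1:**
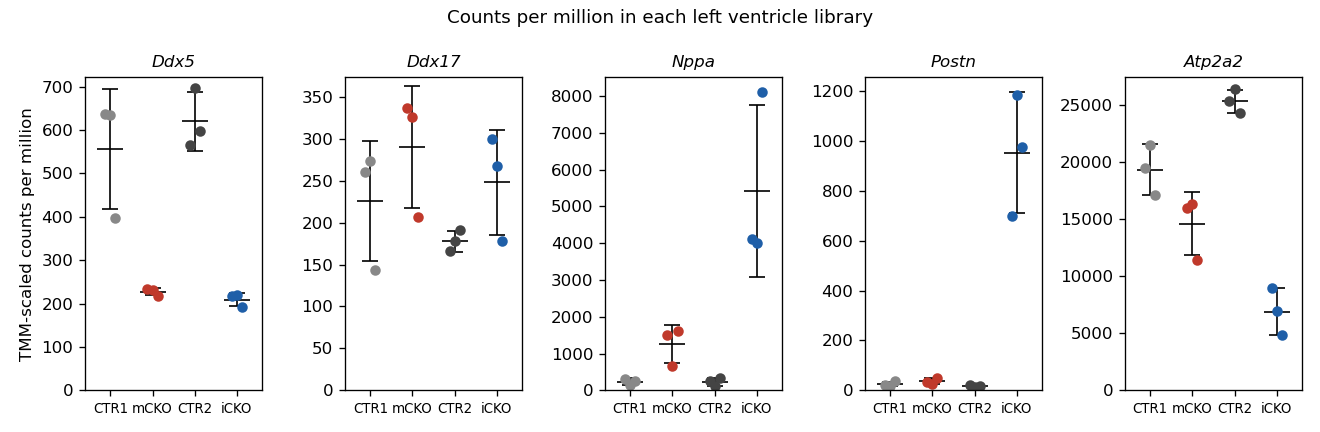
TMM-scaled CPM of Ddx5, Ddx17, Nppa, Postn and Atp2a2 per library (points) in CTR1, mCKO, CTR2 and iCKO, with the mean and SD of each group (n = 3). The 3 mCKO and the 3 iCKO libraries sit below all control libraries for Ddx5.

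The comparison of mCKO with CTR1 asked which transcripts differ in the ventricle when cardiomyocytes lack Ddx5 constitutively. As CTR1 mice lacked Cre, an effect of Myh6-Cre itself cannot be told apart from loss of Ddx5 here. Nppa, which encodes atrial natriuretic peptide, rose 5.15-fold, from 238 ± 85.6 to 1254 ± 512 CPM (SD, n = 3). Lower calls were made for 20 of 30 genes of fatty acid oxidation, 16 of 52 of oxidative phosphorylation and 8 of 18 of ketone or branched-chain amino acid breakdown. Higher calls were made for 20 of 31 extracellular matrix genes, 13 of 18 macrophage markers, 11 of 22 p53 targets and 10 of 22 interferon-stimulated genes. None of these lists was called with an estimated correlation (adjusted p = 0.12 to 0.68 without the replicate block and 0.34 to 0.60 with it). Kcnv2, a modifier subunit of voltage-gated potassium channels, fell (-1.87 ± 0.15, adjusted p = 5.6e-05). These gene calls come from the fit with the replicate number as a block, in which 978 of 13353 tested genes rose and 861 fell. Scaling by library sizes only, with the block, gave 1581 higher and 474 lower genes, 76.9% higher against 53.2%. Lower calls under it numbered 16 for fatty acid oxidation, 8 for oxidative phosphorylation and 8 for ketone or branched-chain amino acid genes. Higher calls numbered 24 for matrix, 14 for macrophage, 12 for p53 and 10 for interferon genes. Most changes were small, as 172 of the higher and 26 of the lower genes passed a 2-fold change. Without the block edgeR called 0 genes, with 1164 at an unadjusted p under 0.05 and a smallest adjusted p of 0.069. DESeq2 called 152 genes higher and 110 lower without the block, and limma-voom called 0. Groups did not overlap for 1027 higher and 975 lower genes, 14.99% of those tested. Chance gives 10% for exchangeable libraries, a value that leaves out the shared deviation of replicate 3.

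The block rests on replicate 3, since replicates 1 and 2 were not told apart by their numbers. Without both replicate 3 libraries and without a block, 514 genes were higher and 526 lower in mCKO. With the block kept, 218 were higher and 170 lower without replicate 3, and 646 higher and 447 lower without replicate 2. Of the 51 genes named here that the block called in mCKO, 46 were called without both replicate 3 libraries and no block, and all 51 kept their direction. The other 5 were Nppa (2.22, adjusted p = 0.28), Ddit4 (-0.74, adjusted p = 0.42), Tnc (0.93, adjusted p = 0.15), Lypd8l (-1.39, adjusted p = 0.12) and Cacna2d2 (0.55, adjusted p = 0.45). The named genes were picked from block calls on these same libraries, so they do not stand for all block calls. With the block kept but without replicate 3, which leaves fewer degrees of freedom, 357 of all 1839 block calls (19.4%) were made again in the same direction. For gene lists below, members are counted with the block. Medians and camera p-values come from the fit without it, and the block changed the camera call of 1 list in mCKO, the atrial markers. In the fit without the block, leaving out 1 replicate 3 library keeps the deviation of replicate 3 in the other group only. List calls lost or gained in that way do not separate the knockout from replicate 3.

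Among 14 stress and fetal-programme genes 5 rose, 2 fell and 7 were not called in mCKO (6 higher and 2 lower, adjusted over the list alone). Ankrd1, a stress-responsive repeat protein of the sarcomere, rose (1.15 ± 0.06, adjusted p = 1.0e-05), whereas Fhl1, a LIM-domain protein, fell (-0.51 ± 0.07, adjusted p = 8.2e-04). The list median was 0.39 (camera adjusted p = 0.014, and 0.47 with an estimated correlation), and its call was lost without CTR1 replicate 2 (adjusted p = 0.20) or mCKO replicate 3 (0.12). Without both replicate 3 libraries 4 members were higher and 1 lower. Of 25 sarcomere genes 7 fell and 0 rose (7 lower over the list alone), including Tnni3, cardiac troponin I (-0.42 ± 0.06, adjusted p = 0.0010), and Myom1, an M-band protein (-0.49 ± 0.06). Calcium-handling genes fell for 7 of 24 members (1 higher and 9 lower, adjusted over the list alone), among them Ryr2, the sarcoplasmic calcium release channel (-0.53 ± 0.06, adjusted p = 3.2e-04), and Atp2a2, the SERCA2 calcium pump (-0.42 ± 0.06). Medians were -0.13 for the sarcomere list (camera adjusted p = 0.017) and -0.13 for the calcium list (0.041), with adjusted p = 0.47 and 0.68 with an estimated correlation. Both calls were lost without CTR1 replicate 1 (adjusted p = 0.084 and 0.086), CTR1 replicate 2 (0.065 and 0.18) or mCKO replicate 3 (0.56 and 0.56). Scaling by library sizes only, with the block, left 5 sarcomere and 6 calcium genes lower, with medians of -0.06 and -0.06. Sarcomere genes also stood lower in mCKO replicate 3 than in replicates 1 and 2, with a median log2 deviation of -0.47 (standard error 0.16 over genes). In CTR1 the median of -0.14 (standard error 0.13) was not told apart from 0.

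Ion channel and conduction genes went both ways, with 4 higher, 6 lower and 15 not called of 25 (4 and 9 over the list alone), and no list call (median -0.10, mean 0.01, camera adjusted p = 0.37). Kcnv2 was among the lower ones. Fatty acid oxidation genes fell for 20 of 30 members (25 adjusted over the list alone) and none rose, with Acadvl, an acyl-CoA dehydrogenase (-0.45 ± 0.06, adjusted p = 0.0011), and Mlycd, malonyl-CoA decarboxylase (-0.47 ± 0.07), as examples. Nuclear oxidative phosphorylation genes fell for 16 of 52 (25 over the list alone), as in Sdha of complex II (-0.37 ± 0.06, adjusted p = 0.0024). Of 18 genes for ketone and branched-chain amino acid catabolism 8 fell (9 over the list alone), led by Acat1, a mitochondrial thiolase (-0.80 ± 0.07, adjusted p = 6.4e-05), and Ivd, isovaleryl-CoA dehydrogenase (-0.48 ± 0.07). Medians were -0.29, -0.14 and -0.17, with camera adjusted p = 5.6e-10, 1.7e-05 and 1.0e-06. With an estimated correlation the adjusted p was 0.35, 0.68 and 0.35, and the oxidative phosphorylation call was lost without CTR1 replicate 3 (0.071). Scaling by library sizes only, with the block, left 16, 8 and 8 members lower. The oxidative phosphorylation median with the block went from -0.15 to -0.08 under that scaling. Replicate 3 deviated for fatty acid oxidation by medians of -0.13 in CTR1 (standard error 0.07) and -0.24 in mCKO (0.11), the former not told apart from 0. For oxidative phosphorylation the medians were 0.26 and 0.40.

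Targets of p53 rose for 11 of 22 members in mCKO (12 higher and 1 lower, adjusted over the list alone), including Eda2r, a TNF receptor family member (1.85 ± 0.15, adjusted p = 5.4e-05), and Phlda3, an inhibitor of Akt (1.89 ± 0.13, adjusted p = 1.7e-04). Without both replicate 3 libraries 7 members were called higher. ATF4 and one-carbon genes rose for 9 of 22 members and fell for 1 (12 and 2 over the list alone). Gdf15, a stress-induced cytokine (2.03 ± 0.23, adjusted p = 3.7e-04), and Phgdh, an enzyme of serine synthesis (2.06 ± 0.31, adjusted p = 0.0024), were higher, and Ddit4, an inhibitor of mTORC1, was lower (-0.83 ± 0.08, adjusted p = 3.2e-04). Interferon-stimulated genes rose for 10 of 22 (11 over the list alone), among them Zbp1, a nucleic acid sensor (0.96 ± 0.19, adjusted p = 0.0086), and Parp14 (0.66 ± 0.10). Without both replicate 3 libraries this list had 16 higher members. Medians were 0.36, 0.44 and 0.75, with camera adjusted p = 1.3e-08, 2.0e-07 and 1.6e-09. The corresponding adjusted p values with an estimated correlation were 0.12, 0.47 and 0.47. Macrophage markers rose in the same libraries for 13 of 18 members, by a median of 0.55.

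Extracellular matrix genes rose for 20 of 31 members (25 adjusted over the list alone) and none fell, with Timp1, an inhibitor of metalloproteinases (1.51 ± 0.13, adjusted p = 9.1e-05), Postn, periostin (0.57 ± 0.08), and Tnc, tenascin C (1.33 ± 0.25), as examples. Macrophage and monocyte markers rose for 13 of 18 (15 over the list alone), among them Csf1r (0.59 ± 0.07, adjusted p = 5.1e-04), C1qb (0.62 ± 0.07) and Mrc1 (0.51 ± 0.08). Fibroblast markers rose for 6 of 14 (6 over the list alone), including Pcolce, which promotes procollagen processing (0.78 ± 0.08, adjusted p = 3.7e-04). The medians were 0.39, 0.55 and 0.23, with camera adjusted p = 1.2e-06, 4.0e-10 and 0.042. With an estimated correlation these were adjusted p = 0.68, 0.47 and 0.73. The matrix call was lost without mCKO replicate 3 (adjusted p = 0.22), and the fibroblast call without CTR1 replicate 1 (0.20), CTR1 replicate 2 (0.29) or mCKO replicate 3 (0.90). Without both replicate 3 libraries 15 matrix, 10 macrophage and 3 fibroblast genes were higher. Replicate 3 exceeded replicates 1 and 2 in both groups by medians of 0.91 and 0.86 for matrix genes (CTR1 and mCKO), 0.44 and 0.58 for macrophage markers, 0.46 and 0.53 for fibroblast markers and 0.70 and 0.67 for endothelial markers.

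Splicing regulators fell for 5 of 33 members in mCKO (5 over the list alone), including Rbfox1, which directs muscle exon choice (-1.22 ± 0.09, adjusted p = 4.8e-05). The list median was -0.12 (camera adjusted p = 0.01, and 0.74 with an estimated correlation). Its call was lost without CTR1 replicate 1 (adjusted p = 0.094), CTR1 replicate 2 (0.16) or mCKO replicate 3 (0.72), and 1 member was lower without both replicate 3 libraries. Scaling by library sizes only, with the block, left 1 splicing regulator lower and moved the median with the block from -0.11 to -0.04. Skeletal muscle markers rose for 3 and fell for 1 of 6 tested (5 and 1 over the list alone, median 0.87, camera adjusted p = 1.0e-06, and 0.12 with an estimated correlation). Tnni2, fast troponin I (1.26 ± 0.20, adjusted p = 0.0026), and Mybpc2, fast myosin-binding protein C (1.08 ± 0.13), were among the higher ones. Cell cycle genes rose for 3 of 23 (3 over the list alone, median 0.29, camera adjusted p = 0.0011, and 0.47 with an estimated correlation), with the list call lost without mCKO replicate 1 (0.063) and no member called without both replicate 3 libraries. Atrial markers, of which 2 of 9 rose, were called by camera with the block (adjusted p = 5.0e-04, and 0.41 with an estimated correlation) but not without it (adjusted p = 0.30). Cytosolic ribosomal protein genes were higher for 2 of 76 (1 over the list alone, median 0.09, camera adjusted p = 0.53). Replicate 3 exceeded the others in this list by medians of 0.73 in CTR1 and 0.97 in mCKO, and leaving out mCKO replicate 3 gave a median of -0.31 (adjusted p = 3.9e-07). The list was called as higher without CTR1 replicate 3 (0.38, adjusted p = 5.9e-05), mCKO replicate 1 (0.24, 0.0030) or mCKO replicate 2 (0.24, 0.0039).

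Outside the lists, Dgki, a diacylglycerol kinase, rose from 0.372 ± 0.146 to 4.61 ± 0.651 CPM (SD, n = 3) and Atp2b2, a plasma membrane calcium pump, rose by 2.83 ± 0.33 (adjusted p = 0.0017) in mCKO. Mt3, a metallothionein, was higher (2.04 ± 0.25). Dmd, dystrophin (-1.25 ± 0.17, adjusted p = 0.014), and Clcn1, a chloride channel (-1.76 ± 0.15), were lower. No camera call was made for glycolysis and glucose uptake (3 higher of 24, including Eno1 at 0.62 ± 0.07, adjusted p = 2.7e-04; list camera adjusted p = 0.37), cytosolic heat shock (2 higher and 1 lower of 13, 0.058) or cardiac transcription factors (3 lower of 23, including Esrra at -0.47 ± 0.07, 0.078). Adrenergic and natriuretic signalling had 1 lower member of 21, Adra1b (-0.73 ± 0.07), with a median of 0.03 against a lower camera direction (adjusted p = 0.35). DEAD-box helicases other than Ddx5 had 1 higher and 1 lower of 31 (camera adjusted p = 0.33). Immediate early genes had 1 and 1 of 16 (0.82), and endoplasmic reticulum chaperones (0 of 17, 0.33) and circadian clock genes (0 of 16, 0.70) had none. The median signs of the glycolysis, chaperone, DEAD-box, clock and immediate early lists turned with the scaling in mCKO, and the clock mean (0.06) was opposite to its median and camera direction. Endothelial (1 higher of 18, camera adjusted p = 0.82), smooth muscle (1 of 13, 0.97), lymphocyte and neutrophil (0 of 8, 0.30), erythroid (0 of 7, 0.33), adipocyte (0 of 4, 0.79), Schwann cell (1 lower of 7, 0.61) and sex-linked transcripts (0 of 4, 0.53) were not called as lists. Leaving out 1 library brought calls for chaperones (without CTR1 replicate 2, adjusted p = 0.0058), heat shock (mCKO replicate 1, 0.023), erythroid markers (mCKO replicate 2, 0.0023) and endothelial markers (CTR1 replicate 3, 0.020). Cardiac transcription factors were called as lower without CTR1 replicate 3 (adjusted p = 0.036), mCKO replicate 1 (0.0053) or mCKO replicate 2 (0.023).

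**Figure D2:**
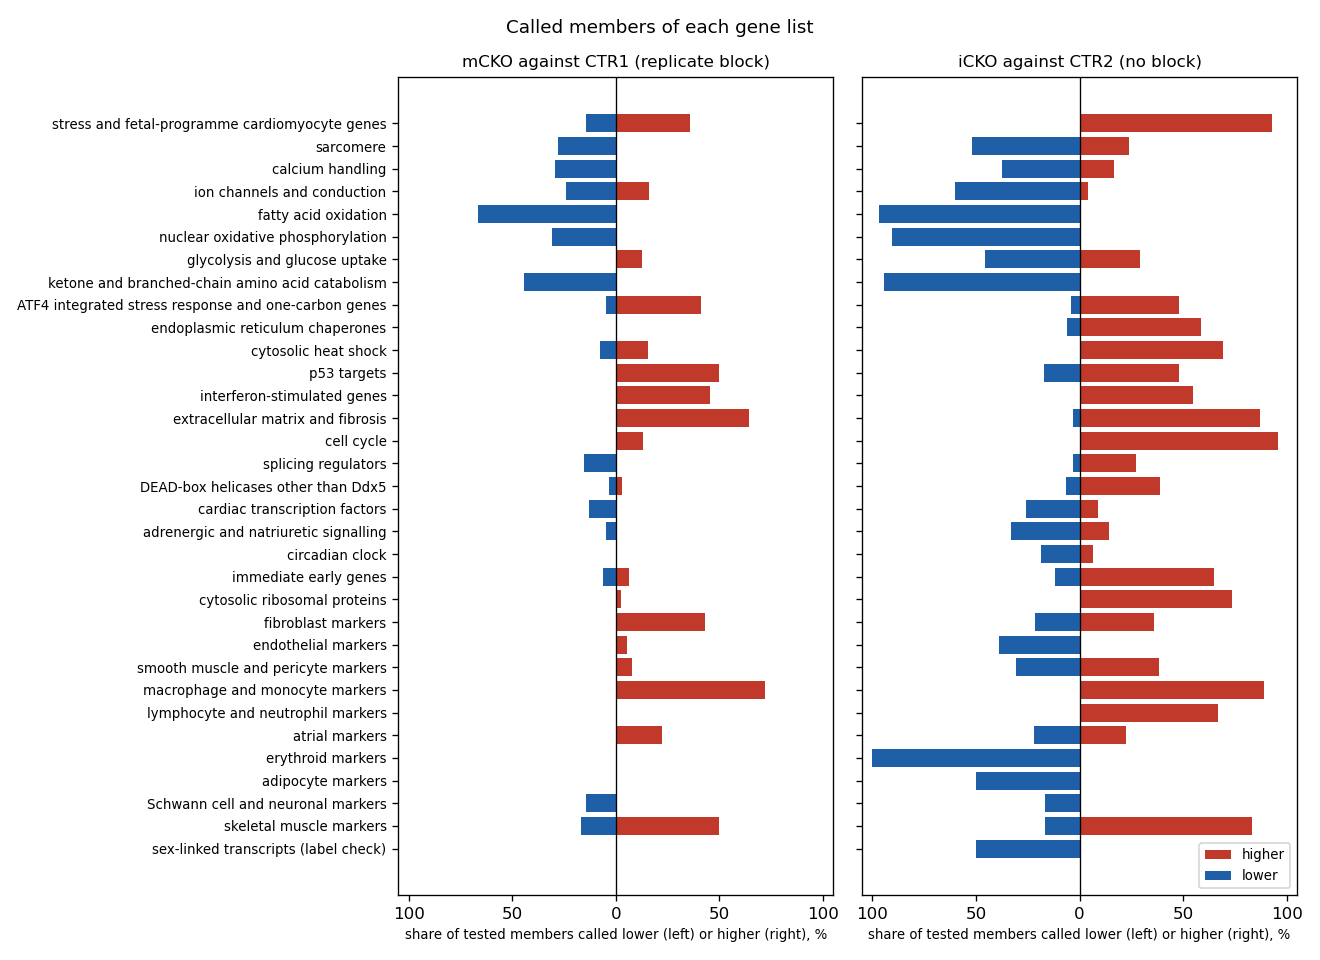
Share of tested members of each gene list that were called lower or higher (adjusted p under 0.05) in mCKO against CTR1 with the replicate block and in iCKO against CTR2 without a block. In iCKO 29 of 30 fatty acid oxidation genes were lower and 27 of 31 extracellular matrix genes higher. Median signs of the glycolysis, chaperone, DEAD-box, clock and immediate early lists in mCKO, and of the glycolysis and adipocyte lists in iCKO, turned with the scaling.

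The comparison of iCKO with CTR2 asked how the ventricle responds when Ddx5 is deleted acutely, with both groups given tamoxifen. As CTR2 mice lacked Cre, an effect of activated MerCreMer cannot be told apart from loss of Ddx5 here. Extracellular matrix genes rose for 27 of 31 members, as Postn went from 17.5 ± 4.43 to 952 ± 243 CPM (54.5-fold) and Tnc from 1.93 ± 0.24 to 371 ± 97.8 CPM (192-fold; SD, n = 3). Nppa rose 23.0-fold, from 235 ± 107 to 5412 ± 2340 CPM. Among genes of mitochondrial fuel use, 29 of 30 for fatty acid oxidation and 47 of 52 for oxidative phosphorylation fell, and Kcnip2, a subunit of the transient outward potassium channel, fell from 255 ± 16.4 to 5.85 ± 3.09 CPM. Of cell cycle genes 24 of 25 rose, of macrophage markers 16 of 18, and of immediate early genes 11 of 17, with 2 lower. No list was called in iCKO with an estimated correlation (lowest adjusted p = 0.098). Of 13548 tested genes 3420 rose and 2648 fell, of which 2026 and 1321 changed more than 2-fold. Groups did not overlap for 4321 higher and 3662 lower genes, 58.9% of those tested, against 10% by chance. Scaling by library sizes only moved the median over all genes from 0.03 to 0.24 and gave 4592 higher and 1832 lower genes, 71.5% higher against 56.4%.

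Stress and fetal-programme genes rose for 13 of 14 members in iCKO (13 over the list alone, median 2.94, camera adjusted p = 3.5e-10, and 0.098 with an estimated correlation), with Nppa (4.53 ± 0.45, adjusted p = 2.0e-04), Ankrd1 (3.15 ± 0.63) and Fhl1 (2.11 ± 0.17) as examples. Sarcomere genes were divided, with 13 lower, 6 higher and 6 not called of 25 (13 and 6 over the list alone, camera adjusted p = 0.075). Tnni3 (-1.63 ± 0.20, adjusted p = 4.2e-04), Myom1 (-1.10 ± 0.14) and Myom2 (-2.08 ± 0.17) fell, while the actin crosslinker Flnc (2.58 ± 0.21, adjusted p = 9.2e-05) and the small heat shock protein Cryab (1.84 ± 0.22) rose. Calcium-handling genes were lower for 9 and higher for 4 of 24 (9 and 4 over the list alone, median -0.29, camera adjusted p = 0.0074, and 0.44 with an estimated correlation). Scaling by library sizes only gave 8 lower and 5 higher calcium-handling genes, with a median of -0.08. Ryr2 (-2.19 ± 0.27, adjusted p = 4.5e-04), Atp2a2 (-1.88 ± 0.22), the SERCA2 inhibitor phospholamban Pln (-1.94 ± 0.14) and the calcium-binding protein Hrc (-2.62 ± 0.20) fell together. Ion channel genes fell for 15 and rose for 1 of 25 (15 and 3 over the list alone, median -0.91, camera adjusted p = 6.4e-06, and 0.44 with an estimated correlation). Kcnv2 (-6.72 ± 0.46, adjusted p = 6.1e-05) and Kcnip2 (-5.45 ± 0.38) were the lower examples. In the same libraries macrophage markers had a median log2 fold change of 1.72 and endothelial markers of -0.47.

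Fatty acid oxidation genes fell for 29 of 30 members in iCKO (29 over the list alone), including Hadhb of the trifunctional protein (-2.01 ± 0.14, adjusted p = 6.9e-05), Mlycd (-2.23 ± 0.15), Acadvl (-1.67 ± 0.15) and lipoprotein lipase, Lpl (-2.27 ± 0.18). Nuclear oxidative phosphorylation genes fell for 47 of 52 (49 over the list alone), with Sdha (-1.36 ± 0.15, adjusted p = 2.8e-04) and the ATP synthase gene Atp5a1 (-1.37 ± 0.14) as examples. Of 18 ketone and branched-chain amino acid genes 17 fell (17 over the list alone), among them Bdh1, beta-hydroxybutyrate dehydrogenase (-2.40 ± 0.19, adjusted p = 9.0e-05), Acat1 (-1.41 ± 0.14) and Ivd (-1.46 ± 0.15). Medians were -1.65, -0.98 and -1.44, with camera adjusted p = 2.5e-24, 6.3e-16 and 4.9e-14. With an estimated correlation these were adjusted p = 0.098, 0.44 and 0.14. Glycolysis and glucose uptake genes were divided, with 7 higher and 11 lower of 24 (8 and 11 over the list alone, camera adjusted p = 0.14), and their median sign turned with the scaling. Eno1, enolase 1 (1.67 ± 0.18, adjusted p = 2.9e-04), and Slc16a3, a lactate exporter (3.28 ± 0.27), rose, whereas the muscle phosphofructokinase Pfkm fell (-2.05 ± 0.19). Leaving out CTR2 replicate 3 left 4 higher glycolysis genes, and leaving out iCKO replicate 2 left 7 lower ones. Cardiac transcription factors fell for 6 and rose for 2 of 23 (median -0.25, camera adjusted p = 0.037, and 0.53 with an estimated correlation), as in Esrra, a regulator of mitochondrial genes (-1.22 ± 0.14, adjusted p = 3.4e-04). That list call was lost without CTR2 replicate 2 (adjusted p = 0.055) or iCKO replicate 3 (0.071). Scaling by library sizes only gave 4 higher and 6 lower members of that list, with a median of -0.03. Macrophage markers rose in these libraries by a median of 1.72.

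Extracellular matrix genes rose for 27 and fell for 1 of 31 members in iCKO (28 and 1 over the list alone, median 3.25, camera adjusted p = 5.2e-28, and 0.098 with an estimated correlation). Tnc (7.58 ± 0.29, adjusted p = 1.0e-05), Timp1 (6.84 ± 0.29), Postn (5.77 ± 0.30) and Tgfb2, a transforming growth factor (3.69 ± 0.19), were among them. Macrophage and monocyte markers rose for 16 of 18 (16 over the list alone, camera adjusted p = 9.5e-10, and 0.44 with an estimated correlation), with Ccr2, a monocyte chemokine receptor (4.09 ± 0.21, adjusted p = 2.0e-05), C1qb (1.71 ± 0.33), Csf1r (1.43 ± 0.16) and Mrc1 (1.60 ± 0.17) as examples. Lymphocyte and neutrophil markers rose for 4 of 6 (camera adjusted p = 0.03, and 0.44 with an estimated correlation), a call lost without iCKO replicate 3 (adjusted p = 0.054). Fibroblast markers had 5 higher and 3 lower of 14 (camera adjusted p = 0.23), including Pcolce (2.24 ± 0.21, adjusted p = 1.5e-04). Endothelial markers fell for 7 of 18, as in the receptor kinase Tie1 (-0.89 ± 0.14, adjusted p = 0.0012), with a median of -0.47 (camera adjusted p = 0.048, and 0.57 with an estimated correlation). Scaling by library sizes only gave 3 lower and 1 higher endothelial markers, with a median of -0.26. Without CTR2 replicate 2, CTR2 replicate 3 or iCKO replicate 1 the lower endothelial markers numbered 3, 4 and 4, and the list call was lost without CTR2 replicate 2 (adjusted p = 0.12) or iCKO replicate 1 (0.081). Erythroid markers fell for 8 of 8 (median -2.33, camera adjusted p = 0.021, and 0.57 with an estimated correlation), but for 0 without CTR2 replicate 2 (list adjusted p = 0.052), 3 without iCKO replicate 1 and 0 without iCKO replicate 2. Smooth muscle (5 higher and 4 lower of 13, camera adjusted p = 0.54), atrial (2 and 2 of 9, 0.65), Schwann cell (1 lower of 6, 0.44), adipocyte (1 lower of 2, 0.80) and sex-linked lists (2 lower of 4, 0.27) were not called. The adipocyte median changed sign with the scaling, and the atrial median (-0.28) was opposite to its mean and camera direction.

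Cell cycle genes rose for 24 of 25 members in iCKO (24 over the list alone, median 2.22, camera adjusted p = 1.8e-08, and 0.44 with an estimated correlation), including Mcm5 of the replicative helicase (2.22 ± 0.23, adjusted p = 2.1e-04) and Top2a, topoisomerase II alpha (2.93 ± 0.37). Macrophage markers rose in the same libraries for 16 of 18 members, by a median of 1.72, beside this and the following lists. Cytosolic heat shock genes rose for 9 of 13 (camera adjusted p = 7.1e-05, and 0.098 with an estimated correlation), with Hspb1 going from 165 ± 20.7 to 2458 ± 831 CPM (SD, n = 3). Endoplasmic reticulum chaperones rose for 10 and fell for 1 of 17 (11 and 1 over the list alone, camera adjusted p = 0.022, and 0.57 with an estimated correlation), a list call lost without CTR2 replicate 2 (adjusted p = 0.082). ATF4 and one-carbon genes rose for 11 and fell for 1 of 23 (camera adjusted p = 0.0013, and 0.44 with an estimated correlation), among them Gdf15 (3.67 ± 0.36, adjusted p = 1.7e-04), Psat1 (2.49 ± 0.23) and Phgdh (1.29 ± 0.28). Immediate early genes rose for 11 and fell for 2 of 17 (camera adjusted p = 3.8e-05, and 0.44 with an estimated correlation), with the transcription factor Egr1 as an example (2.82 ± 0.34, adjusted p = 4.1e-04). Interferon-stimulated genes rose for 12 of 22 (12 over the list alone, camera adjusted p = 0.0040, and 0.60 with an estimated correlation), including Zbp1 (2.81 ± 0.43, adjusted p = 0.0013) and Isg15 (2.17 ± 0.32), while Parp14 was not called (0.18 ± 0.33, adjusted p = 0.68). Targets of p53 rose for 11 and fell for 4 of 23 (11 and 5 over the list alone) with no list call (camera adjusted p = 0.084, but 0.041 without iCKO replicate 1), and the higher ones included Phlda3 (2.68 ± 0.21) and Eda2r (2.18 ± 0.21).

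Cytosolic ribosomal protein genes rose for 56 of 76 in iCKO (60 over the list alone, median 0.90, camera adjusted p = 7.3e-06, and 0.62 with an estimated correlation), as in Rpl3 (1.98 ± 0.21, adjusted p = 2.6e-04). This number dropped to 19, 23 and 13 without CTR2 replicate 1, 2 or 3. The macrophage marker median in these libraries was 1.72. Skeletal muscle markers rose for 5 and fell for 1 of 6 tested (camera adjusted p = 2.2e-09, and 0.098 with an estimated correlation), with slow troponin T, Tnnt1, going from 14.1 ± 1.73 to 592 ± 109 CPM and Mybpc2 rising by 4.19 ± 0.20. Splicing regulators rose for 9 and fell for 1 of 33 (camera adjusted p = 0.30), with Ptbp1 higher (1.01 ± 0.14, adjusted p = 8.8e-04) and Rbfox1 lower (-3.49 ± 0.29). DEAD-box helicases other than Ddx5 rose for 12 and fell for 2 of 31 (camera adjusted p = 0.15), and the higher ones numbered 6 without CTR2 replicate 1 and 7 without CTR2 replicate 3. Adrenergic and natriuretic genes had 3 higher and 7 lower of 21 (camera adjusted p = 0.059, but 0.045 without CTR2 replicate 2 and 0.022 without iCKO replicate 1), led by the alpha-1A receptor gene Adra1a (-3.18 ± 0.26, adjusted p = 9.6e-05). Circadian clock genes had 1 higher and 3 lower of 16 (camera adjusted p = 0.33), with 7 lower without iCKO replicate 1. Outside the lists, Asb14 (-6.25 ± 0.37, adjusted p = 4.2e-05), Armc2 (-5.99 ± 0.32) and Yipf7 (-3.38 ± 0.14) were among the lower genes and the reticulon gene Rtn4 (3.36 ± 0.15) among the higher. Arg1, arginase 1, rose from 0.0981 ± 0.0851 CPM in CTR2, under the level that 3 counts give, to 35.7 ± 40.1 CPM in iCKO (SD, n = 3; adjusted p = 8.7e-04), with 10.4, 14.8 and 81.8 CPM in its libraries, and no fold is given. Esr1, the oestrogen receptor gene, held 29990, 18566 and 4416 counts in iCKO and 5 to 59 counts in each of the other libraries (8.06 ± 0.75, adjusted p = 1.5e-04).

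The models were compared to ask which responses they share and where they differ. Among 13121 genes tested in both, 560 rose in both (230 by chance, one-sided Fisher p = 3.7e-125) and 565 fell in both (173 by chance, p = 9.5e-203), with the block in mCKO. Fisher's test takes genes as independent, which they are not, so these p-values do not measure the spread between libraries. Opposite calls were fewer than chance gives, with 78 genes higher in mCKO and lower in iCKO and 26 the other way (193 and 205 by chance). With the block in both models these numbers were 540, 547, 74 and 22, and without it the overlap was 0 because edgeR called 0 genes in mCKO, where 1164 had an unadjusted p under 0.05. Without both replicate 3 libraries and without the block, 647 genes shared a direction and 60 did not. The correlation of log2 fold changes between the models was 0.46 (Pearson) and 0.46 (Spearman) across genes, which are not independent replicates. Nppa, Ankrd1, Gdf15, Phlda3, Eda2r, Timp1 and Mt3 were higher and Ddx5, Kcnv2, Rbfox1, Dmd, Clcn1, Ryr2 and Acat1 lower in both. Controls lacked Cre in both models, so shared changes do not separate loss of Ddx5 from an effect of the recombinase. Genes called in opposite directions included Fhl1, Ubxn10 (1.37 ± 0.17 in mCKO and -3.76 ± 0.47 in iCKO), Lypd8l (-1.41 ± 0.20 and 2.57 ± 0.25), Ahrr (0.57 ± 0.15 and -3.02 ± 0.34) and the calcium channel subunit Cacna2d2 (0.67 ± 0.16 and -2.55 ± 0.58).

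A test of the difference, the mCKO effect minus the iCKO effect, called 1521 of 13871 genes with a positive and 1371 with a negative difference, 1002 and 965 of them by more than 2-fold. With library sizes only these were 1103 and 2145 (34.0% positive against 52.6%, with the median over all genes moving from 0.03 to -0.14), and without mCKO replicate 1 the negative ones numbered 910. Fatty acid oxidation genes fell less in mCKO, with 29 of 30 differing (median 1.36, camera adjusted p = 3.3e-24, and 0.032 with an estimated correlation), as did ketone and branched-chain amino acid genes (15 of 18, median 1.15, 2.7e-13, and 0.046 with an estimated correlation). Stress and fetal-programme genes had lower effects in mCKO than in iCKO (10 of 14, median -2.32, camera adjusted p = 1.2e-08, and 0.046 with an estimated correlation). Extracellular matrix genes did so for 22 of 31 and the reverse for 1 (median -2.74, camera adjusted p = 2.4e-20, and 0.22 with an estimated correlation). With the replicate block the calls at an estimated correlation were lost, with adjusted p = 0.12 for fatty acid oxidation, 0.18 for ketone and branched-chain amino acid genes and 0.12 for stress genes. No difference was called for Ddx5 itself (0.32 ± 0.25, adjusted p = 0.39), Eda2r (-0.28 ± 0.25, adjusted p = 0.46), Phgdh (0.91 ± 0.65, adjusted p = 0.34) or Mt3 (0.11 ± 0.49, adjusted p = 0.89). The interferon-stimulated list (0 of 22 members, camera adjusted p = 0.32) was not called. Nor was the p53 list (0.98), whose members went both ways, with 4 positive and 7 negative differences of 23 and a median of 0.03 against a mean of -0.18. The interferon list was called without mCKO replicate 1 (adjusted p = 0.040) or iCKO replicate 3 (0.039). Of single genes, Postn (-5.18 ± 0.46, adjusted p = 5.4e-05) and Tnc (-6.08) rose less in mCKO than in iCKO, and Kcnip2 (5.37 ± 0.42, adjusted p = 3.1e-05) fell in iCKO without a call in mCKO (-0.14 ± 0.07, adjusted p = 0.21). Conversely Dgki (5.41 ± 0.79, adjusted p = 8.4e-04) and Atp2b2 (4.52), too low for a test within the iCKO experiment, were higher in mCKO. The models also differed in treatment, Cre and library set, and the age of the iCKO and CTR2 mice is not given in the sources used here. Whether counting used strand is not given in the sources used here, so values of genes whose exons overlap another gene are uncertain, among them Nppa (61.5% of exonic bases), Pln (59.6%), Acadvl (42.9%), Rtn4 (18.4%), Cryab (17%), Csf1r (15.1%), Bdh1 (13.7%), Pfkm (10.2%), Ptbp1 (9.22%), Clcn1 (8.2%) and Mybpc2 (5.32%).

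**Figure D3:**
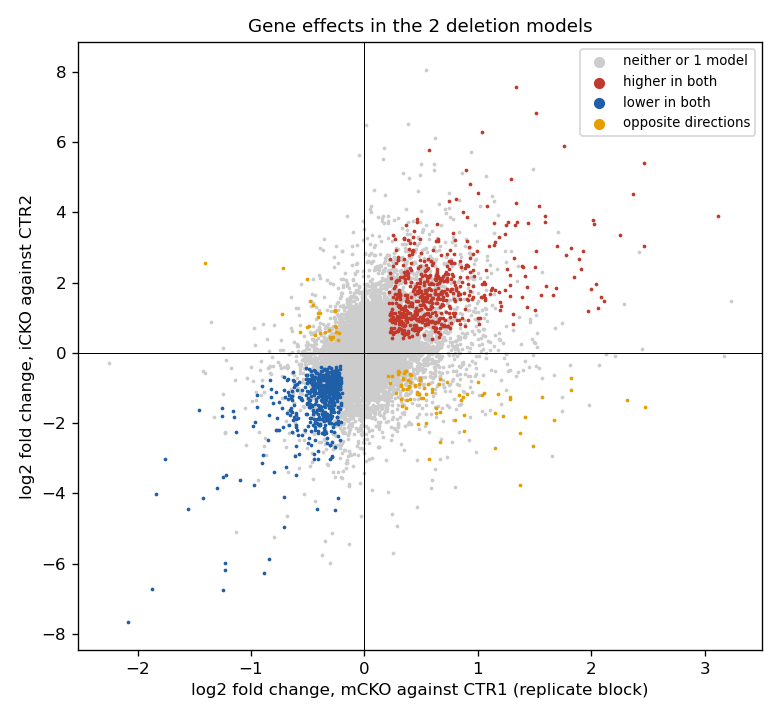
Log2 fold change of each gene tested in both models, mCKO against CTR1 with the replicate block and iCKO against CTR2, coloured by call. Across genes r was 0.46, with 560 genes higher in both and 565 lower in both.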

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

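The Esr1 tests and the removal of a gene length trend in this part were chosen only after the result was seen. All results here are differences between the models, the mCKO effect minus the iCKO effect, past an interaction test with adjusted p under 0.05. They numbered 2892 genes in all, and 57 of the genes named in the text are listed, with adjusted p from 2.2e-06 to 0.035 (edgeR). Left out of the list were 3 named genes with 0 counts in a whole group, for which a fitted difference is no bound, of which Arg1 (adjusted p = 0.012) and Hkdc1 (0.018) passed the test and Aqp3 did not. The rule for named genes holds 147 such genes, so the 57 are not a full account.

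Among contractile, channel and stress genes the log2 difference was -2.11 for Nppa, -2.60 for Fhl1, -2.49 for Flnc, -1.81 for Cryab, 1.24 for Tnni3 and 2.20 for Myom2. It was 1.70 for Ryr2, 1.51 for Atp2a2, 1.84 for Pln, 2.36 for Hrc, 4.89 for Kcnv2, 5.37 for Kcnip2, 3.25 for Cacna2d2 and 2.91 for Adra1a. Metabolic genes differed by 1.25 (Acadvl), 1.80 (Mlycd), 1.75 (Hadhb), 2.15 (Lpl), 0.65 (Acat1), 1.02 (Ivd), 2.57 (Bdh1), 1.03 (Sdha), 1.13 (Atp5a1), 0.79 (Esrra), 1.96 (Pfkm), -1.02 (Eno1) and -3.05 (Slc16a3). Matrix and immune genes differed by -5.30 (Timp1), -5.18 (Postn), -6.08 (Tnc), -3.46 (Tgfb2), -1.42 (Pcolce), -0.80 (Csf1r), -3.71 (Ccr2), -1.05 (Mrc1) and, for the endothelial gene Tie1, 0.92. For stress, growth and RNA genes the values were -1.60 (Gdf15), -1.53 (Psat1), -3.70 (Hspb1), -1.95 (Mcm5), -2.93 (Egr1), -1.50 (Rpl3), 2.32 (Rbfox1) and -0.93 (Ptbp1). Skeletal muscle genes differed by -4.73 (Tnnt1), -2.44 (Tnni2) and -3.08 (Mybpc2). The others were Dgki (5.41), Atp2b2 (4.52), Esr1 (-7.48), Asb14 (5.41), Armc2 (5.73), Ubxn10 (5.20), Lypd8l (-3.95), Ahrr (3.64), Yipf7 (3.19) and Rtn4 (-3.08). Dgki and Atp2b2 were too low for a test within the iCKO experiment, so the iCKO part of their differences rests on low counts.

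Camera called 19 of 33 lists for a difference, 5 of them with an estimated correlation and none with that and the replicate block (lowest adjusted p = 0.12). Median differences above 0 were 0.28 for calcium handling, 1.42 for ion channels, 1.36 for fatty acid oxidation, 0.88 for oxidative phosphorylation, 1.15 for ketone and branched-chain amino acid catabolism, 0.27 for glycolysis and 2.31 for erythroid markers. Those below 0 were -2.32 for stress and fetal-programme genes, -0.71 for endoplasmic reticulum chaperones, -0.38 for heat shock, -2.74 for extracellular matrix, -1.73 for cell cycle, -0.30 for splicing regulators, -0.19 for other DEAD-box helicases, -2.13 for immediate early genes and -0.78 for ribosomal proteins. Cell-type and muscle lists below 0 were macrophage markers (-1.12), lymphocyte and neutrophil markers (-1.24) and skeletal muscle markers (-2.76). The glycolysis call was lost without CTR1 replicate 3 (adjusted p = 0.088), mCKO replicate 2 (0.079), CTR2 replicate 2 (0.092), iCKO replicate 1 (0.071) or iCKO replicate 2 (0.068). With the replicate block the glycolysis (adjusted p = 0.052) and erythroid (0.061) calls were lost, and 0 of 7 erythroid markers were called with or without it. The splicing call was lost without CTR1 replicate 2 (0.052) or mCKO replicate 3 (0.19), and the DEAD-box call without mCKO replicate 3 (0.075). The lymphocyte and neutrophil call was lost without CTR1 replicate 1 (0.061), CTR1 replicate 3 (0.071), CTR2 replicate 2 (0.064) or iCKO replicate 3 (0.065).

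More genes were called in iCKO than in mCKO. A smaller spread between the iCKO libraries was argued against, since the median absolute log2 fold change was 3.79 times that of mCKO while the common coefficients of variation without a block were 0.209 in iCKO and 0.222 in mCKO. Gene length bias was argued against, since 95.2% of called iCKO genes were called in the same direction after a length trend was taken out. A lower share of cardiomyocyte RNA as the cause was not decided, as marker lists of other cells went both ways. Macrophage markers had a median of 1.72. Endothelial markers had one of -0.473 (standard error 0.124 over genes), or -0.259 with library sizes only. Myh6 took 3.82 to 4.15% of counts in CTR2 and 1.21 to 2.57% in iCKO, which does not separate cell share from expression. A change in macrophages themselves stays open. Also open is an effect of tamoxifen-activated MerCreMer itself, as 0 libraries of MerCreMer mice with intact Ddx5 were analysed here. Acute against constitutive loss, treatment and any difference in age were not tested and stay open too.

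Esr1 counts in the iCKO libraries may come from the MerCreMer transgene, which contains the ligand-binding domain of the oestrogen receptor, since the lowest iCKO library exceeded the highest other library 55.7-fold in CPM, TMM-scaled over the 12 libraries. Tamoxifen alone was argued against by the log2 fold change of 8.06 over CTR2, which received it too. Loss of Ddx5 in itself was argued against by the difference of -7.48 (standard error 1.13, adjusted p = 0.0011, edgeR) between mCKO and iCKO. As every iCKO library carried both the transgene and the acute loss of Ddx5, an effect of acute loss was not tested and stays open. Esr1 stood at 1059, 639.8 and 168 CPM in iCKO replicates 1, 2 and 3, and at 3.01 CPM in the highest other library.

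Other splits of the samples were counted for each number of called genes. For mCKO without the block 10 of 10 splits gave as many genes (real 0, highest other 0), with the block 1 of 4 (real 1839, highest other 0), and for iCKO 1 of 10 (real 6068, highest other 0), each too few for a share under 0.05. For the difference between models 10 of 100 draws gave as many genes as the real 2892, the highest other giving 5859, so that chance is not excluded for that count as such. The 9 other large draws kept iCKO apart from CTR2 and mixed mCKO with CTR1 (lowest 3030), and the 90 draws that mixed iCKO with CTR2 gave at most 0. Splits that mixed iCKO with CTR2 gave 0 genes in the iCKO experiment alone too, and mixing mCKO with CTR1 takes away only the mCKO effect. These draws thus cannot decide whether the count of differences exceeds chance.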

How the results depend on the processing

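Replicate 3 as a batch term, leaving out both libraries of a number, the alternatives run with the block and the block in mCKO only were chosen after seeing the data. Ddx5 was lower under every setting run, from -1.18 to -1.48 in mCKO and from -1.35 to -1.64 in iCKO, and always called in iCKO. In mCKO it became called with DESeq2 (-1.30, adjusted p = 1.4e-06), the block (-1.26, 0.0019), all 12 libraries in 1 fit (-1.30, 0.013), the batch term (-1.26, 6.8e-04) and without both replicate 3 libraries (-1.45, 8.7e-06). The count of 0 in mCKO (edgeR, 1164 at an unadjusted p under 0.05, limma-voom 0) became 262 with DESeq2 (152 higher, 110 lower), 4 without the low-count filter (3 and 1), 1839 with the replicate block (978 and 861), 24 in 1 fit of all 12 libraries (18 and 6), 2053 with the batch term (1056 and 997) and 1040 without both replicate 3 libraries (514 and 526). Leaving out 1 library gave 0 to 1, the 1 without mCKO replicate 3. Taking the block result of 1839 as the start, DESeq2 gave 1030 (455 higher), a 2-fold threshold 198 (172 and 26), and library sizes only 1581 higher and 474 lower. With the block but without both libraries of replicate 1, 2 or 3 the count was 1508 (766 and 742), 1093 (646 and 447) or 388 (218 and 170), where 2 pairs leave fewer degrees of freedom.

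In iCKO the 2-fold threshold left 3347 genes (2026 and 1321), and leaving out a library gave 4302 to 6770. Replicate numbers did not pair the iCKO libraries (r = 0.0583, -0.0896 and -0.161), not every library correlated best with its own number, and the block called 5491 genes (3055 and 2436). Within iCKO, replicate 3 stood apart, with a chi-square per degree of freedom of 146 and 112 against replicates 1 and 2, which gave 23.4 between them. Its deviation correlated across genes with those of CTR1 and mCKO replicate 3 (r = 0.311 and 0.362). That of CTR2 replicate 3 did so at -0.172 and -0.139. For the difference between models the 2-fold threshold left 1002 positive ones, library sizes only gave 2145 negative ones, the block gave 3901 in all, and leaving out a library gave 2064 to 3220, with 910 to 1615 negative, the lowest without mCKO replicate 1. Genes called in both models in 1 direction, 0 without the block, numbered 168 with DESeq2, 2 without the filter, 1087 with the block, 1125 with the block in mCKO only and 647 without both replicate 3 libraries. Those in opposite directions were 22, 0, 96, 104 and 60, and 0 to 1 without 1 library. The ribosomal protein list in mCKO ranged over medians of -0.31 to 0.38 when 1 library was left out, against 0.09 with all, and was reversed without mCKO replicate 3 (-0.31, adjusted p = 3.9e-07). Replicate 3 exceeded replicates 1 and 2 in this list by medians of 0.73 in CTR1 and 0.97 in mCKO. Leaving out 1 of these libraries keeps that deviation in the other group only. The median was then 0.38 without CTR1 replicate 3 and -0.31 without mCKO replicate 3. Such moves in mCKO thus do not separate the knockout from replicate 3. For the other moves, apart from thresholds and fewer libraries, the cause was not tested.

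Over all lists and settings, the estimated correlation and fry included, 339 list calls in mCKO were unchanged, 45 lost, 11 gained and 1 reversed. In iCKO 290 were unchanged, 30 lost and 10 gained, and for the difference 484, 31 and 13. Of the lists camera called in mCKO, fry called only the p53 targets and the skeletal muscle markers, and neither with the block (adjusted p = 0.067 and 0.094). In iCKO fry lost the interferon, ribosomal and erythroid lists. It gained the sarcomere, splicing and DEAD-box lists (adjusted p = 0.014 each), the p53 targets (0.013), glycolysis (0.020) and the adrenergic list (0.047). For the difference fry lost the splicing, ribosomal and erythroid lists and gained the adrenergic list (0.043). With the block the glycolysis (adjusted p = 0.052) and erythroid (0.061) lists lost and the endothelial list (0.017) gained a called difference, the adrenergic list gained a call in iCKO (0.039) and the atrial list in mCKO (5.0e-04), and no other list call by camera at the preset correlation changed. At an estimated correlation the block ended the 5 calls for the difference, with adjusted p = 0.12 for fatty acid oxidation, stress and skeletal muscle genes, 0.18 for ketone and branched-chain amino acid genes and 0.26 for heat shock. The genes given by the naming rule had 3561 unchanged calls in iCKO, 117 lost and 28 gained, and none of those named in the report lost its iCKO call. In mCKO, where none was called without the block, 3871 were unchanged and 416 gained. Removing mitochondrially encoded genes gave no value, since the tables as used here held none. Depth limits low genes, as 3 counts over a library correspond to 0.106 to 0.157 CPM. Simulated 1.5-fold changes were recovered at 2% in mCKO without the block, 4% in iCKO and 2% for the difference. They were made only in genes with average log2 CPM of at least 1, so that recovery does not measure the limit set by depth.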

Other observations

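The tests of length and of cardiomyocyte share as the whole cause, the Ddx17 values and the Gene Ontology terms in this part were chosen only after the result was seen. Terms of the tricarboxylic acid cycle followed the mitochondrial lists, with 26 of 29 genes lower in iCKO (median -1.19, camera adjusted p = 6.3e-13, and 0.72 with an estimated correlation) and 13 of 29 lower in mCKO with the block (median -0.21, adjusted p = 1.8e-05, and 0.88 with an estimated correlation). Peroxisomal genes were lower for 62 and higher for 16 of 118 in iCKO (median -0.58, adjusted p = 1.4e-05, and 0.72 with an estimated correlation), and lower for 28 and higher for 9 of 119 in mCKO (adjusted p = 0.021, and 0.88). Chemokine-mediated signalling genes were higher for 20 and lower for 1 of 29 in iCKO (median 2.15, adjusted p = 3.4e-08, and 0.72 with an estimated correlation) and higher for 8 of 25 in mCKO (median 0.50, adjusted p = 0.0013, and 0.88). Neutrophil chemotaxis genes were higher for 36 and lower for 5 of 56 in iCKO (median 1.79, adjusted p = 1.1e-08, and 0.72 with an estimated correlation). In all 144 terms were called up and 31 down of 2228 in mCKO with the block, and 194 up and 60 down of 2264 in iCKO, and 0 with an estimated correlation in either. The terms, tested by camera in limma, share genes with each other and with the lists.

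Some genes of the naming rule had no counts in CTR2. Hkdc1, a hexokinase-like gene, had 0 counts over the CTR2 libraries and 397 over iCKO, at least 97.1-fold higher in TMM-scaled CPM against a floor of 3 counts over the group. Aqp3, an aquaporin gene, had 0 and 338 counts, at least 82.7-fold higher on the same floor. The rise of Ddx17 in mCKO with the block, 0.38, exceeded the median over all tested genes by 0.38.

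Replicate 3 of both mCKO and CTR1 stood apart from replicates 1 and 2. GC content was argued against as the cause, with a Spearman rho across genes of 0.0932 in CTR1 and 0.104 in mCKO, and gene length as the whole cause was argued against because the deviations of the 2 groups still correlated at 0.813 (0.825 before) once a length trend was removed. A lower share of cardiomyocyte RNA in replicate 3 stays open as a partial cause, since all 4 non-myocyte marker lists had medians above 0 but the lowest, smooth muscle in CTR1 at 0.293 (standard error 0.346), was not told apart from 0. As the whole cause it was argued against only by nuclear oxidative phosphorylation genes, abundant in cardiomyocytes, which stood higher by at least 0.257. Sarcomere (-0.14 in CTR1 and -0.47 in mCKO) and fatty acid oxidation genes (-0.13 and -0.24) went the other way. Myh6 took 2.01% of counts in CTR1 replicate 3 and 1.61% in mCKO replicate 3, against 4.09 to 4.60% in replicates 1 and 2. The lists thus do not settle whether a lower share was the whole cause. Gene length as a partial cause stays open (rho of -0.293 in CTR1 and -0.342 in mCKO), and as the labels name no group or batch for replicate 3, no biological explanation was tested.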
